A study of Mus musculus with 2 samples.

How the data were processed

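Polyadenylated RNA from the adrenal gland of an adult female C57BL/6J mouse aged 10 weeks was sequenced as 2 libraries. Per the labels, both libraries are technical replicates of 1 biological sample, and replicate 2 was added in 2015, later than the first. RNA was extracted with a kit for lipid-rich tissue, per the labels' protocols. The libraries therefore form 1 group, and library and date cannot be separated. No error given here covers differences between animals.

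For each library the authors deposited a gene table and a transcript table. Expected counts in the deposited tables are estimated numbers of fragments per gene or transcript and need not be whole. TPM values, named so per the file headers, stand beside them and by definition share 1 fixed sum per library, so a gene's TPM falls when other genes take more of that sum. FPKM values in the deposited tables were used only as an alternative for the number of detected genes. Posterior mean TPM and the bounds of its interval, which carry no fixed range and were treated as a score, are also given by the deposited tables. The share of each transcript within its gene is given in percent in the deposited transcript tables. Per the deposited notes on the files, reads were placed on the mm10 assembly with GENCODE annotation M4 and the quantifications came from alignments to the transcriptome. The aligner, the counting program and their versions are not given in the sources used here, and a text note per library was not used for values. Every table belonged to a library named in the labels.

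Gene tables held 69691 rows, of which 43346 were Ensembl genes, 97 were spike-in controls and 26248 were other entries. All spike-in and other rows had a count of 0 in both libraries and were left out. Symbols were found for 42462 Ensembl genes in the reference name table. Coordinates, transcript sequences and GC content came from GENCODE M21 on GRCm38, the assembly also called mm10, so the annotation release differs from that of the tables. Of 103639 Ensembl transcripts, 101510 were found in M21, and 90.1% of these had the same length there. Gene GC content is the length-weighted mean over the M21 transcripts of a gene. Nuclear copies of mitochondrial genes were 15 genes with a transcript matching a mitochondrial one at 90% identity or more over at least 50% of its length (BLAST 2.17.0). A near-identical copy of any other gene was a match of at least 95% identity over at least 50% of the longest transcript.

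Replicate 1 held 28267651 rounded expected counts and replicate 2 held 17376660. After removal of mitochondrial genes and their nuclear copies, 13260900 and 14716667 counts remained. Intervals are exact (Clopper-Pearson) at 95% and, like the floor of 3 counts used where a library is at 0, cover counting error only. TPM was also rescaled over nuclear genes, leaving out mitochondrial genes and their copies.

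Detected genes had a TPM of at least 1 in both libraries. For the comparison of the libraries, expected counts were rounded and genes with a summed count of at least 20 were kept, which left 14358. Library sizes were scaled with TMM (edgeR 4.0.16 in R 4.3.3). Each gene was tested with a two-sided exact binomial test conditional on its summed count, Benjamini-Hochberg adjusted over all tested genes, and called at an adjusted p under 0.05 with a fold of at least 2. This test compares the libraries, not conditions or animals. Passing means being called, so a gene that did not pass may have missed only the fold minimum. Without that minimum 12592 genes were called. Log2 ratios are of replicate 2 to replicate 1 with a prior count of 0.5. TMM assumes that most genes do not differ, which the spread reported for these libraries does not meet, so directions are relative to that scaling. On simulated data for this comparison with 200 changed genes, 90.8% of those changed by 1.5 and 100% of those changed by 3 on the log2 scale were called, and 0 of 14022 unchanged genes were called among 14218 tested. The simulation held counting error only, with no GC trend or other spread between libraries, and was tested with the scaling that generated it. Its rates are therefore not error rates for these libraries. Sampling noise was simulated 20 times.

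Gene lists (28 lists with 266 entries, all of which were found) and 8 gene pairs were fixed before the data were examined, as were the tests and the alternatives except those named as added. A list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 classes but not on GC content. Genes were named by a rule fixed at the same time: in each list up to 5 members with the highest and 1 with the lowest mean TPM, all steroidogenic and sex-linked members, the genes of each pair, the 10 genes with the highest mean TPM, the 10 called genes with the largest ratio in each direction among those with a mean TPM of at least 1, and the transcripts with extreme shares. Some genes that this rule names, and the ratio of 1 pair, are not reported here. Trends with GC content and gene length were removed with a lowess curve of span 0.2 (statsmodels 0.14.6). A call held after GC correction if the same test, with the trend taken off, passed in the same direction. Other computations used Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.

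Alternatives were DESeq2 1.42.0 size factors, scaling by total count, other count and TPM minimums, FPKM, posterior mean values, other pseudocounts, removal of trends with GC content and length, edgeR's exact test with the dispersion of the pair, and leaving out each library. Rescaling without mitochondrial genes together with their nuclear copies was added after seeing the data. Paralogs and pseudogenes that share sequence, among them Cyp11b1 and Cyp11b2, Hsd3b1 and Hsd3b6, Cyp21a1, the globin genes, Hspa1b, the histone genes and the mitochondrial genes with their copies, carry counts that an estimation step divided between them and are uncertain to that extent.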

Results

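Polyadenylated RNA of 1 mouse adrenal gland sample was measured in 2 technical replicate libraries, called replicate 1 and replicate 2. The adrenal gland holds a steroid-producing cortex around a catecholamine-producing medulla. The libraries held 28267651 and 17376660 expected counts, rounded per gene, assigned to 17503 and 18609 genes. With 1 biological sample, SDs over n = 2 libraries describe technical spread.

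Genes of the mitochondrial genome led the transcript pool, and their share differed between the libraries. They took 40.1% of counts in replicate 1 (95% exact binomial interval 40.04 to 40.08) and 10.6% in replicate 2 (10.63 to 10.66). Nuclear copies of mitochondrial genes took another 13.0% and 4.66%. The 10 genes with the highest mean TPM were mt-Atp8, mt-Co1, mt-Nd2, mt-Nd1 and mt-Nd4, which encode subunits of the respiratory chain and ATP synthase, and the nuclear copies Gm28661, Gm10925, Gm28437, Gm28438 and Gm10222 on chromosome 1. mt-Co1 reached 76069 TPM in replicate 1 and 40590 TPM in replicate 2. For Gm28661 the deposited interval in replicate 1 ran from 40599 to 74576 TPM, and reads are shared between it and the mitochondrial genome. All 13 listed mitochondrially encoded mRNAs were lower in replicate 2, with a median log2 ratio of -3.18 that was -2.05 under total-count scaling, -5.22 with the length trend removed, -0.82 with the GC trend removed and -1.23 with both removed. Of the 13 calls, 5 held without the GC trend. The least abundant, mt-Nd6, stood at 921 and 362 TPM.

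In all, 9106 genes reached a TPM of 1 in both libraries, 8774 of them protein-coding. Replicate 1 had 9202 such genes and replicate 2 had 13486, and 4380 genes reached the minimum in replicate 2 alone. After rescaling over nuclear genes, an alternative added after seeing the data, 12147 genes reached it in both.

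Steroidogenic genes held the highest nuclear ranks in both libraries: after rescaling over nuclear genes Hsd3b1 ranked 1 in each, Star 2 and 3, and Cyp11b1 3 and 6, while Cyp21a1 ranked 280 in replicate 1 and 2 in replicate 2. Hsd3b1, which encodes the 3β-hydroxysteroid dehydrogenase of the adrenal, stood at 7002 ± 5842 TPM (SD, n = 2), Star, the carrier of cholesterol into mitochondria, at 3671 ± 2431 TPM, and Cyp11b1, the 11β-hydroxylase of corticosterone synthesis, at 3536 ± 2357 TPM. On scaled counts these genes did not differ by 2-fold, at 1.08, 0.768 and 0.774 times in replicate 2 relative to replicate 1. Of the 10 members tested, 5 were higher in replicate 2 and none was lower. Cyp21a1, the 21-hydroxylase, was 26.6-fold higher (97.0 and 9131 TPM), Fdxr, which passes electrons to mitochondrial P450 enzymes, 49.6-fold (12.8 and 833 TPM), Cyp11b2, the aldosterone synthase, 24.6-fold (2.89 and 256 TPM), Por, the reductase of microsomal P450 enzymes, 10.3-fold (13.2 and 122 TPM) and Cyp11a1, the side-chain cleavage enzyme, 6.61-fold (263 and 4097 TPM). With the GC trend removed the log2 ratio went from 4.73 to 1.38 for Cyp21a1, from 5.63 to 1.72 for Fdxr, from 4.62 to 2.67 for Cyp11b2, from 2.72 to 1.98 for Cyp11a1 and from 3.37 to -0.15 for Por, whose call ended, and Fdx1 newly passed at 2.11. That new call rests on a mean of 44.7% GC over the M21 transcripts of Fdx1. Its only transcript in the deposited tables has 49.4% GC, and no correction with that value was made, so the call is uncertain. Fdx1 at 1.97-fold and Hsd3b6 at 1.54-fold did not pass. Cyp17a1, the 17α-hydroxylase, had 0 and 2 counts, which is at or under the floor of 3 counts. The list's median log2 ratio was 1.85, above 99.97% of matched random lists, and 0.99 after removal of the trend with GC content.

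**Figure D1:**
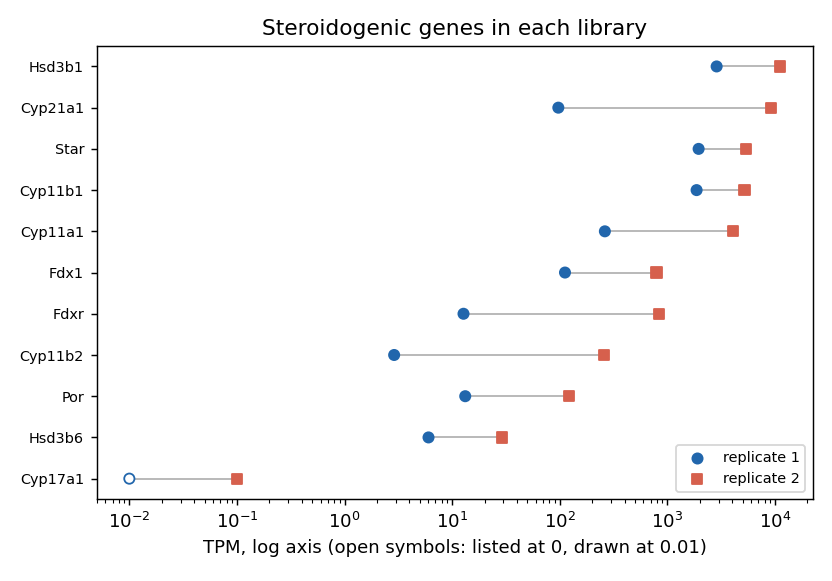
TPM of the 11 steroidogenic genes in replicate 1 (circles) and replicate 2 (squares) on a log axis, with open symbols for genes listed at 0. Star lies at 1953 and 5390 TPM, while Cyp21a1 lies at 97.0 and 9131 TPM.

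Of 12 genes that supply cholesterol, 10 reached a TPM of 1 in both libraries. Scarb1, the receptor for high-density lipoprotein, stood at 32.5 and 1230 TPM, and Apoe, an apolipoprotein, at 2.09 and 740 TPM. Soat1, which esterifies cholesterol, stood at 105 and 218 TPM, and Lipa, the lysosomal lipase, at 91.1 and 214 TPM. On scaled counts both were lower in replicate 2, at log2 ratios of -0.99 and -0.61, and missed the 2-fold minimum. Plin2, a lipid droplet protein, was 7.50-fold higher in replicate 2 and Stard3 47.5-fold. Of 12 tested members 7 were higher in replicate 2 and 2 lower. In cholesterol synthesis 8 of 19 were higher and 5 lower: Dhcr7 was 5.19-fold and Fdps 6.67-fold higher, while Hmgcs1 and Msmo1 were at 0.370 and 0.419 times. Mvd was at 0 and 223 counts. Without the GC trend, 6 of the 7 higher and none of the 2 lower calls held in cholesterol supply (Scarb1 3.47 to 1.89 on the log2 scale, Apoe 6.10 to 1.54), and 6 of the 8 higher and none of the 5 lower calls in synthesis (Dhcr7 1.29, Fdps 1.61, Hmgcs1 -0.09). Among genes of the response to corticotropin, Mc2r, its receptor, was at 245 and 351 TPM and its accessory protein gene Mrap at 10.8 and 563 TPM. In that list 2 of 10 members were higher, 4 were lower and 4 did not pass, with Gnas at 862 ± 801, Prkar1a at 184 ± 88.1, Prkar2b at 142 ± 12.4 and Creb1 at 12.3 ± 1.499 TPM (SD, n = 2). GC correction left 1 higher and none of the lower calls in this list, with Mc2r from -1.33 to 0.19 and Mrap from 3.83 to 1.35, and Gnas newly passed at -3.31.

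Markers of the cortical zones were present, with lists split between directions. For the zona glomerulosa, the outer aldosterone-producing zone, 3 members were higher in replicate 2 (Cyp11b2, Wnt4 at 13.3-fold and Kcnk9 at 31.7-fold) and 3 were lower, among them Dab2 at 0.412 and Vsnl1 at 0.368 times. Mcoln3 had 0 and 2 counts. All 3 lower calls ended after GC correction (Dab2 -0.24, Vsnl1 -0.01, Agtr1b 0.01), as did that of Wnt4 (0.90). In the zona fasciculata list Akr1b7 was 2.97-fold and Mrap 14.3-fold higher, Mc2r was at 0.397 times, and Cyp11b1 and Abcb1b did not pass. The calls of Akr1b7 and Mrap held after GC correction and that of Mc2r ended. X-zone genes, which mark an inner zone of the mouse cortex, were also divided: Akr1c18 (720.5 ± 271 TPM; SD, n = 2) and Pik3c2g were lower in replicate 2, and Cyp2f2 and Sbsn were higher by 7.02-fold and 14.6-fold. The lower calls ended after GC correction (Akr1c18 from -1.07 to 0.23, Pik3c2g from -1.44 to 0.03) and the higher ones held. Transcriptional regulators of the cortex gave 4 higher and 4 lower of 10, with Nr5a1, which encodes steroidogenic factor 1, 16.3-fold and Wnt4 13.3-fold higher, and Cited2 and Gata6 at 0.405 and 0.495 times. With the GC trend removed the log2 ratio of Nr5a1 went from 4.03 to 0.04, and the list's median went from -0.20 to -1.40, below all 10000 random lists. None of its 4 higher calls held, 2 of them turning to lower, 3 of the 4 lower calls held, and 2 members newly passed as lower. Gata4 had the lowest mean of that list, 0.84 TPM. In the renin and angiotensin list 3 of 7 were higher and 2 lower. Agtr1a stood at 105 ± 51.6, Agtr2 at 11.3 ± 1.23 and Agtr1b at 7.06 ± 1.77 TPM (SD, n = 2), with Agt 11.6-fold higher and Ren1 at 0 and 54 counts. Only the call of Ren1 held after GC correction, and Agt went from 3.50 to 0.47.

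Chromaffin genes of the medulla were detected in both libraries, 17 of 20 at a TPM of at least 1. Chgb and Scg2, secretory granule proteins, stood at 1079 ± 1097 and 694 ± 422 TPM (SD, n = 2), and Npy, a neuropeptide, at 475 ± 471 TPM, and none of these passed the test. Chga was 18.1-fold and Th, the first enzyme of catecholamine synthesis, 19.6-fold higher in replicate 2. Pnmt, which makes adrenaline and lies at chromosome 11, 98386450 to 98388181 (GRCm38), had 0 counts in replicate 1 and 4291 in replicate 2, at least 1059-fold higher. In the list 8 members were higher in replicate 2, 3 lower and 9 did not pass, and Ret had the lowest mean, 0.36 TPM. Its median log2 ratio was 0.57, and -0.68 after removal of the GC trend, so its direction depended on that correction. Of its higher calls 3 held (Th at 1.52, Dbh at 1.72, Pnmt from 12.63 to 7.90), 2 ended (Chga from 4.18 to 0.47) and 3 turned to lower, 1 of the 3 lower calls held, and 5 members newly passed as lower, among them Chgb and Npy at -1.04 each and Ret at -2.13.

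**Figure D2:**
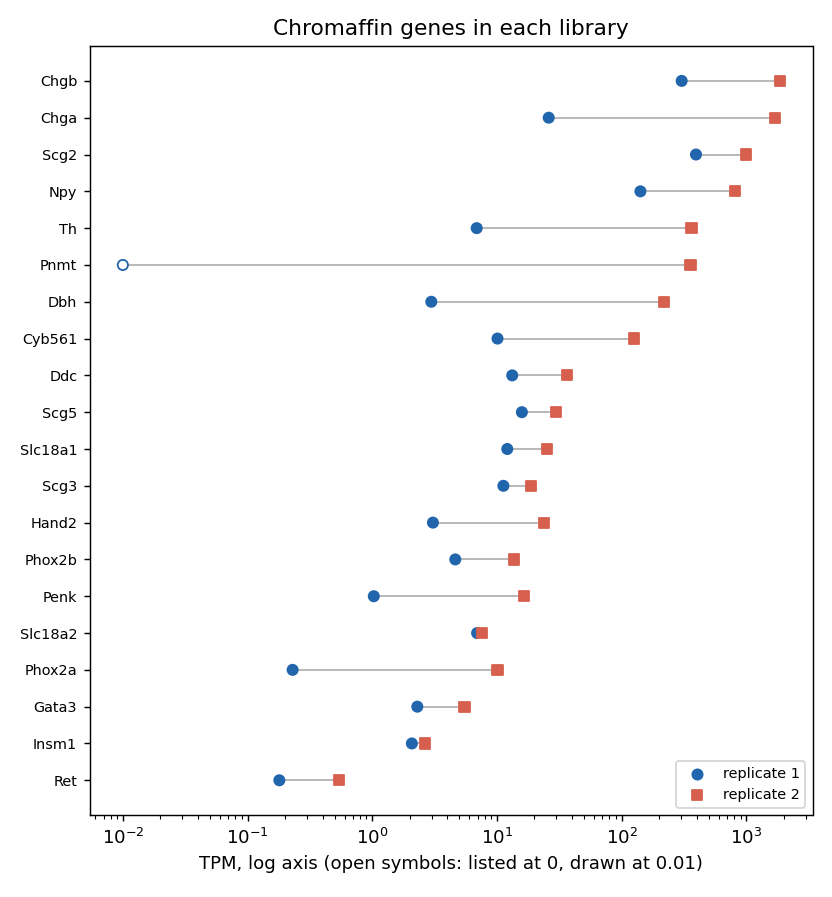
TPM of the 20 chromaffin genes in replicate 1 (circles) and replicate 2 (squares) on a log axis, with open symbols for genes listed at 0. Chgb lies at 303 and 1854 TPM, and Pnmt is listed at 0 in replicate 1 and at 357 TPM in replicate 2.

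Markers of other cell types differed mostly toward replicate 2. All 5 erythroid members were higher there, with Hba-a2 at 24.3 and 1117 TPM, Hbb-bs at 22.8 and 1039 TPM and Hbb-bt at 1.34 and 190 TPM, and the 2 counts of Hba-a1 in replicate 1 stood against 3911. Alas2, of heme synthesis, was 3.39-fold higher. All 5 skeletal muscle members were higher, with Ckm at 3 and 1196 counts, Acta1 at 7 and 1211, Mylpf 31.0-fold, Tnnt3 3.30-fold and Myh4 3.88-fold. Of 10 adipocyte members 5 were higher and none lower: Cfd was 92.5-fold and Cidec 18.6-fold higher, while Fabp4 (335 and 1443 TPM), Ucp1 (69.1 and 420 TPM), Adipoq (55.2 and 211 TPM) and Lep (0.28 and 1.49 TPM) did not pass. In the endothelial list 8 of 12 were higher and 1 was lower, with Plvap 25.9-fold, Egfl7 21.2-fold, Eng 31.3-fold and Cldn5 71.1-fold higher, Emcn at 0.372 times and Kdr at 0.814 times. With the GC trend removed the log2 ratios of Plvap, Egfl7 and Eng were -0.08, 0.70 and 1.31, that of Emcn went from -1.43 to 0.14, and 2 of the 8 higher calls and not the lower one held. Macrophage genes gave 6 higher and 1 lower of 10, with C1qa, C1qb and C1qc higher by 15.3-fold, 25.7-fold and 23.0-fold, Cd68 by 5.74-fold, and Lyz2 and Cd163 not past the test. Capsule and stroma genes gave 3 higher and 3 lower of 10, with Dcn (117 ± 47.7 TPM; SD, n = 2), Col1a2 and Col3a1 not past it, Nr2f2 and Lum lower and Gli1 at 1 and 63 counts. Glial genes were low, with Mbp at 0.93 and 6.33 TPM, S100b at 0.26 and 4.15, Fabp7 at 0.54 and 2.61, Erbb3 at 0.41 and 1.54 and Gfap at 0.14 and 0.65, and 3 of 8 were higher and 1 lower. Of the higher calls, GC correction left 3 of 5 for erythroid cells (Hba-a2 ended at 0.20), 3 of 5 for muscle (Myh4 and Tnnt3 ended), 4 of 5 for adipocytes, 4 of 6 for macrophages (C1qa ended at -0.50), 1 of 3 for capsule and stroma and 1 of 3 for glia, and of the lower calls in these lists only that of Nr2f2. Newly passing were Fabp4, Ucp1, Lyz2, Col1a2 and Fabp7 as higher and Mbp and Gfap as lower.

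Marker lists of kidney, liver, ovary, lymphocytes and, apart from Cela1, pancreas had low sums. The adipocyte and skeletal muscle lists did not, at 480 and 3526 TPM and at 11.1 and 322 TPM in replicates 1 and 2. Kidney markers summed to 0.17 and 0.43 TPM over 10 genes, with Kap highest at 0.14 and 0.38 TPM, Slc22a6 below it, and Umod, Slc34a1 and Miox at 0 counts in both libraries. Liver markers summed to 0.26 and 2.08 TPM, with Alb, newly called higher after GC correction, at 0.19 and 0.99 TPM, and ovary markers to 0.62 and 3.01 TPM, with Oosp1 at 0.58 and 2.10 TPM. Among pancreas genes Cela1 was 18.7-fold higher in replicate 2 (1.28 and 86.3 TPM; log2 ratio 4.20, and 2.38 after GC correction), and Pnlip, the next, was at 0.14 and 0.56 TPM. Lymphocyte markers summed to 0.48 and 3.72 TPM, with Nkg7 at 0 and 1.16 TPM. Xist, the RNA of the inactive X chromosome, stood at 65.9 and 60.4 TPM, and on scaled counts was lower in replicate 2 (log2 ratio -2.13), a call that ended after GC correction (-0.43). The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d had at most 2 counts, for a sample labelled female.

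Stress, antioxidant and proliferation genes were measured as further lists. Of 14 immediate early and heat shock genes 8 were higher in replicate 2 and none lower, with Nr4a1 at 5.98 and 170 TPM and Hspa1b at 8.05 and 72.4 TPM, while Jun, Egr1, Dusp1 and Fosb did not pass. Their median log2 ratio was 1.23, and -1.44 after removal of the GC trend, with 1 of the 8 calls held, 3 turned to lower and 5 newly passing as lower, among them Jun (-1.72), Egr1 (-1.98) and Fosb (-2.22). Of 12 antioxidant genes 5 were higher, with Sod1 3.74-fold, Gpx4 16.5-fold and Gpx1 30.1-fold, and Prdx3 (568 ± 457 TPM), Cat (284 ± 136 TPM) and Gsr (17.6 ± 9.72 TPM; SD, n = 2) did not pass. The antioxidant median was 0.47, and -0.085 after removal of the GC trend, with 3 of the 5 calls held (Gpx4 ended at 0.08) and 2 newly passing as lower, among them Cat. Proliferation genes were low, with Cdk1 at 6.19 ± 4.20, Top2a at 4.93 ± 2.32, Ccna2 at 3.63 ± 0.134, Ccnb1 at 2.54 ± 1.53, Mki67 at 2.45 ± 0.891 and Bub1 at 0.855 ± 0.120 TPM (SD, n = 2), and 1 of 8 was higher and 4 lower in replicate 2, none of which held after GC correction, while 1 newly passed as higher. Among RNAs that mostly lack a poly(A) tail, Hist1h2bc stood at 93.0 and 243 TPM, Hist1h1c at 7.07 and 100 TPM, Rn7sk at 0.41 and 23.7 TPM and Hist1h4h at 0 and 10.2 TPM, Rpph1 had 0 and 2 counts, and Hist1h2ae had none. None of the 3 calls in this list held after GC correction.

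Ratios of paired genes depended on the library for several pairs. The TPM ratio of Cyp11b1 to Cyp11b2 was 647 in replicate 1 and 20.3 in replicate 2, a mean log2 ratio of 6.84 ± 3.53 (SD, n = 2). Hsd3b1 exceeded Hsd3b6 by 476 and 380 times, and Mc2r exceeded Agtr1b by 42.2 times in both. Agtr1b was at 0.0852 and 0.0589 times Agtr1a. Akr1b7 was at 0.871 times Akr1c18 in replicate 1 and at 5.40 times in replicate 2, so the order of this pair changed between the libraries. Pnmt to Th was 0.981 in replicate 2 with Pnmt at 0 in replicate 1, and no ratio is given for Cyp21a1 to Cyp17a1, whose denominator is at or under the floor. These ratios were not corrected for GC content, which was 47.7% for Cyp11b1 and 54.2% for Cyp11b2. It was 48.8% for Akr1b7 and 43.8% for Akr1c18, 47.6% for Hsd3b1 and 49.7% for Hsd3b6. Mc2r was at 42.6%, Agtr1b at 43.6% and Agtr1a at 48.5%. The ratios therefore describe each library and are not estimates for the gland.

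Between the libraries 5232 genes were higher in replicate 2 and 3987 lower, of 14358 tested. Of the genes higher in replicate 2, 283 had 0 counts in replicate 1. Those with the largest ratios were Pnmt, Uqcr11 and Ndufa13 of the respiratory chain, Rpl36 of the ribosome, Ncln, Mbd3, Dhx30, Map3k11 and Med25. Among them Rpl36 has a near-identical copy elsewhere, so its counts may have been divided with that copy. Their 95% exact lower limits lay between 179-fold for Med25 (exact binomial test, adjusted p = 3.55e-214) and 861-fold for Pnmt. The log2 ratios of these 9 genes were 10.37 to 12.63, and 5.73 to 9.11 without the GC trend. Rpl8, a ribosomal protein gene at chromosome 15, 76904078 to 76906314, had 1 and 5375 counts, a ratio of 3980 (95% exact interval 714 to 157242), and its log2 ratio went from 11.37 to 8.01 without the GC trend. At the other end, Gm28439, a nuclear copy of a mitochondrial gene, was 5377-fold lower in replicate 2. Gm14440, Gm28037, Gm12693, Zfp708, Gm6829, Gm4294 and Gm12978, each with a near-identical copy elsewhere, had 0 counts in replicate 2. So did ENSMUSG00000103508.1, which has no M21 entry. For these genes the 95% exact limits ran from at least 23.9-fold to at least 461-fold lower. Gm2274, which also has a near-identical copy, had 1 count in replicate 2, a 167-fold lower value with an interval of 29.5 to 6667. Without the GC trend the log2 ratios of Gm28439, Gm2274 and the 7 copied genes at 0 counts were -9.75 to -5.99. Scaling by total count raised all log2 ratios by 1.14 and gave 7769 higher and 567 lower, and edgeR's exact test with the dispersion of the pair called 0 genes, with 986 at an unadjusted p under 0.05.

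The SD over genes of the log2 ratio was 2.39, against 0.228 from simulated sampling noise. The chi-square per degree of freedom was 1369, so the libraries were not 1 library deposited under both names. The coefficient of variation that edgeR gave for the pair beyond counting error was 0.927. Across the 9106 genes at a TPM of at least 1 in both libraries, Pearson's r of log2(TPM + 1) was 0.674 and Spearman's rho of TPM was 0.615. These correlations are across genes, which are not independent replicates. The log2 ratio followed GC content with a rho of 0.884 over 14274 genes. Of 2762 genes with a GC content of 40 to 45%, 2248 were lower in replicate 2, and of 2721 genes at 55 to 60%, 2471 were higher. Removal of the GC trend left an SD of 1.29 and 3684 called genes, of which 2073 kept their call and direction.

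**Figure D3:**
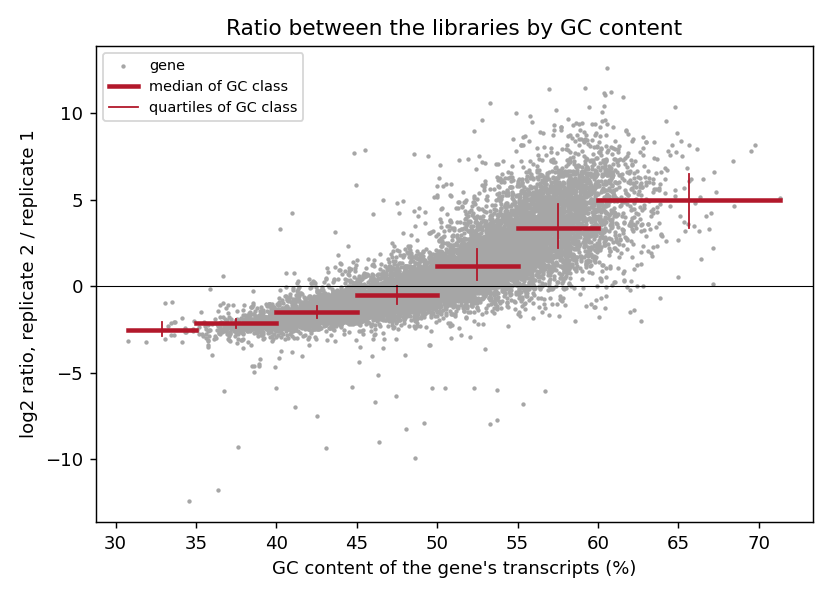
Log2 ratio of replicate 2 to replicate 1 for each tested gene (points) against the GC content of its transcripts in percent, with the median (thick lines) and quartiles (thin lines) of 7 GC classes. The class medians go from -2.52 below 35% GC to 4.99 above 60%.

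Lists differed in where they lay between the libraries. The highest positions, at 97.8% or higher among matched random lists, were those of steroidogenesis, cholesterol supply (1.63), endothelium (2.36), macrophages (2.66), erythroid cells (4.23), adipocytes (1.54), skeletal muscle (4.88) and antioxidants. The mitochondrially encoded list lay below all 10000 random lists. Cholesterol synthesis (0.41), corticotropin signalling (-0.75), cortex regulators (-0.20), zona glomerulosa (0.62), zona fasciculata (-0.37), X-zone (0.87), renin and angiotensin (-0.80), chromaffin, capsule and stroma (-0.35), glia (0.61), immediate early genes, proliferation (-0.85) and RNAs without a poly(A) tail (2.83, or 2.56 with genes at 0 set to their bound) lay above 4.08% to 96.5% of them. With the GC trend removed, the endothelial median was 0.25, at 91.0% of random lists, and the antioxidant median was at 54.0%, cholesterol synthesis (0.40) rose to 98.5%, while immediate early genes and cortex regulators lay below all random lists and chromaffin genes at 0.03%. Median GC content was 55.7%, 55.5% and 53.9% in the last-named lists, and random lists were not matched on it. Some GC-rich genes lay far below the trend, among them Gata6 of the cortex regulators (-4.46). These low positions are therefore not told apart from a poor match of the trend for GC-rich genes. Kidney, liver, pancreas, ovary, lymphocyte and sex-linked lists had fewer than 3 tested members. Adjusted over the list alone, the 26 lists with tested members gave 148 calls, as many as with adjustment over all genes. Of these, 50 of 97 higher and 10 of 51 lower calls held without the GC trend, 9 higher calls turned to lower, and 25 members newly passed. Calls were counted once per list, so genes such as Mrap and Mc2r, in both corticotropin signalling and zona fasciculata, count more than once. Over all tested genes 2073 of 9219 calls held.

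The transcript that led a gene often differed between the libraries. Of 5891 genes with several transcripts and at least 100 counts in each library, 1859 (31.6%) had another leading transcript in the other library. Single-transcript genes such as Star, Cyp11b1, Cyp11b2, Fdx1 and Chga had a share of 100% by construction. Among steroidogenic and chromaffin genes with the smallest leading share, the leading transcript of Fdxr took 5.02% and 91.2%, that of Por 95.8% and 0.498%, that of Hsd3b6 88.1% and 14.6%, that of Ddc 17.6% and 99.5%, and that of Th 24.8% and 100%. The largest changes over all genes were in Aqp7, Tmem176a, Lpcat1, Ccnj and Prkar1b, whose leading transcript went from 0% to 100% of the TPM or the reverse.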

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

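Rescaling without mitochondrial genes and their copies was chosen after seeing the data, and the other alternatives were fixed before. The number of detected genes was 13803 at a TPM minimum of 0.1 and 5015 at 5, as the minimum itself requires, and lay between 9202 and 13486 when a library was left out. With rescaling without mitochondrial genes and their copies the chromaffin median was 61.3 TPM against 20.8 TPM. The spread over genes was 1.52 for the log2 ratio of TPM with a pseudocount of 1, which damps low genes, and other scalings cannot move it. The count of differing genes was 9219, and 3684 with the GC trend removed, 3471 with GC and length trends removed and 0 with edgeR's exact test, whose dispersion was estimated from the same pair and so contains the difference. Other settings of scaling, filter and fold gave 6584 to 12592 genes. The chromaffin shift was -0.68 with the GC trend removed and -0.86 with GC and length trends removed. The count of genes with another leading transcript was 463 at 1000 counts or more, where fewer genes were tested. Removal of trends changed the sign of the median shift for 10 of 22 lists: for 8 with the GC trend removed, 3 with the length trend removed and 8 with both removed. Among these, the antioxidant shift was -0.14 with the length trend, -0.085 with the GC trend and -0.14 with both removed, and that of immediate early genes was -1.44 with the GC trend removed. Star and Cyp11b1, not called, changed sign with the GC trend removed, and Por, which was called, stood at -0.15 with the GC trend removed. Akr1b7 to Akr1c18 lay between -0.20 and 2.43 on the log2 scale when a library was left out. Sign changes under removal of a trend follow from the curve value taken off each gene, which does not tell what causes the trend. The cause of the change in Akr1b7 to Akr1c18 was not tested. Sign changes under total count, in 6 lists, Star (0.75) and Cyp11b1 (0.77), follow from the 1.14 it adds to every log2 ratio and say nothing of stability. Verdicts were tallied for single genes, pairs and lists, without the levels and shifts of the steroidogenesis and chromaffin lists and the pair of Cyp11b1 and Cyp11b2. In this tally 289 values kept their verdict, 19 of them with another sign, 45 moved by more than their spread and 5 counted as reversed. Another 3 single genes newly passed the test, Hsd3b1, Hsd3b6 and Fdx1 under total count and Fdx1 also with the GC trend removed. A list shift kept its verdict within a wide range over its members. For endothelium this range was -0.41 to 4.53 and holds both 2.36 and 0.25, so the tally says little of the stability of list shifts. With 2 libraries, leaving one out moves the mean of a single gene or the mean log2 ratio of a pair by less than 1 SD by construction. For genes and pairs those settings therefore say nothing of stability. List medians can move further, as for capsule and stroma (10.9 TPM against 18.8), lymphocytes (0.025 against 0.23) and pancreas (0.19 against 0.13), and results that compare the libraries have no such setting. No paired analysis was possible because there is 1 group. Depth limits genes with few counts: 3 counts are 0.106 CPM in replicate 1 and 0.173 CPM in replicate 2.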

Other observations

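Tests on transcript length, splice junctions, mitochondrial reads, ribosomal protein genes and near-identical copies were chosen after the results were seen. The design has 1 group and so gives no biological explanation to test. Different cell mixtures were weighed as a difference between the libraries.

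Ribosomal protein and respiratory chain genes were uneven in replicate 1. The 75 nuclear ribosomal protein genes had a median of 31.0 TPM in replicate 1 and 603 TPM in replicate 2, with SDs of log2 TPM over genes of 2.69 and 0.620, and 56 were higher in replicate 2 and 1 lower. The 74 nuclear subunits of oxidative phosphorylation, which include isoforms restricted to some tissues (Cox6a2, Cox6b2, Cox7a1 and Cox8b), had medians of 16.0 and 251 TPM, SDs of 3.18 and 1.41, and 11 were under 1 TPM in replicate 1 against 0 in replicate 2. Both groups were chosen after their values were seen, and 25 of the ribosomal genes have a near-identical copy.

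The log2 ratio between the libraries followed GC content. Mitochondrial reads taking the place of nuclear reads would shift nuclear genes by 1 factor, yet their SD was 2.38, and transcript length and splice junctions leave the relation in place (rho 0.882 at fixed length, and 0.743 among 552 single-exon genes). A loss of GC-rich fragments in replicate 1 is a candidate explanation: within 4318 genes the GC difference of the leading transcripts and the difference of their log2 ratios gave a rho of 0.529, and ribosomal protein TPM followed GC in replicate 1 (rho -0.703) but hardly in replicate 2 (0.0852). If every cell makes all ribosomal proteins, different cell mixtures would keep the proportions of these genes. Their log2 ratios had an SD of 2.79, which argues against mixtures for these genes, though they were chosen after their unevenness was seen. Mixtures stay open for part of the pattern. After the GC trend was removed, 3 of 11 cell type lists (erythroid, adipocyte and skeletal muscle) kept a shift of over 1 beyond matched random lists. This residual shift is not specific to cell type lists, since cholesterol supply (1.19) also shifted by over 1 toward replicate 2. Cortex regulators (-1.40) and immediate early genes (-1.44), both rich in GC (medians 55.5% and 55.7%), shifted in the other direction. Erythroid (3.18) and skeletal muscle (3.32) shifted further than these, so different cell mixtures are neither excluded nor singled out. The erythroid and muscle lists had 5 tested members each. After GC correction Alas2 (0.75) and Hba-a2 (0.20) lay under the other globin genes (3.18 to 6.59), whose counts were divided between paralogs. Tnnt3 (0.63) and Myh4 (0.61) lay under Ckm (4.97), Mylpf (3.80) and Acta1 (3.32), and Ckm and Acta1 had few counts in replicate 1. The labels describe technical replicates of 1 sample, and whether the same RNA was used for both is not given in the sources used here.

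Some GC-rich genes kept their counts in replicate 1, among them Cdkn1c (14078 and 8315 counts), Arf6 (3706 and 1482) and Gas1 (827 and 439), named after their values were seen. Among 3222 genes of at least 55% GC, the lowest GC of any 200-base window went with the log2 ratio at fixed mean GC (partial rho 0.526). An AT-rich stretch from which fragments were still obtained could give this relation. Length was not held fixed, although longer transcripts have more windows and length went with the log2 ratio over all tested genes (rho -0.287). Length and an AT-rich stretch are therefore not told apart here. Single-exon genes lay lower by a further -1.36 on the log2 scale (95% bootstrap interval -1.76 to -0.79, 140 genes). The absence of splice junctions, or something that goes with it, may thus add to the counts kept in replicate 1. Genomic DNA in replicate 1 was not tested.

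Of 83 genes more than 4 below the GC trend, 34.9% had a near-identical copy against 5.13% of the others, and 43.4% had a single exon against 3.64%, with 13 genes in both groups. Reads shared with such copies may account for these 29 genes, which include all 19 with a count of 0 in replicate 2. They do not account for the rest, and 61 of the 83 have at least 55% GC and overlap with the genes of the preceding pattern.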
